A study of Homo sapiens with 6 samples.

How the data were processed

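RNA-seq was done on human primary thyroid cells, which are follicular epithelial cells grown from fresh thyroid tissue that was not tumorous. Per the labels, cells were electroporated with 75 pmol of an siRNA pool against FOXE1 or of a control siRNA pool and lysed 24 h later, at day 5 of culture. The 6 libraries form 2 groups of 3, numbered P1 to P3 in each group, here replicates 1 to 3. Groups were taken from the sample titles and the siRNA target field. The names of the deposited files give the other group for 6 of 6 samples, and FOXE1 itself went against the labels, so groups are called "the libraries labelled siFOXE1" and "the libraries labelled siControl". Were the file names right, every sign given here would be reversed.

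Libraries were made from total RNA after removal of ribosomal RNA with a stranded kit, per the labels. Per the submitters' processing notes, TopHat2, featureCounts and DESeq2 were used with genome build hg19. Versions, the annotation release and the strand setting of the counting are not given in the sources used here, so a gene and an antisense partner may share counts. Each deposited file holds whole-number counts per gene and a further column of signal, the authors' scaled counts as far as the values show. That deposited signal equalled each library's counts times a constant to within a relative 5.1e-15, and the factors lay 0.34% to 0.66% from DESeq2 size factors computed here. Only the counts were tested. The files list 27169 genes with a lowest sum of 5 counts over the 6 libraries, which points to a filter whose rule is not given. Names and gene types came from GENCODE 29 by Ensembl identifier, which named 26630 genes and left 539 without a name. That annotation is on another genome build than hg19. The files list ribosomal DNA genes such as FP236383.2 that an annotation of hg19 would not be expected to hold, so the build behind the counts is uncertain and no coordinates are given.

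Total counts per library were 26897566, 24119998 and 30749733 for replicates 1 to 3 labelled siFOXE1 and 30233263, 31560446 and 26116067 for those labelled siControl. Counts came from reads without molecular identifiers, so an interval from counts alone would cover counting error only, and none is given. The interval of the FOXE1 fold comes from the paired edgeR fit, on 19.1 moderated degrees of freedom. It takes in variation of the within-pair difference from pair to pair. The paired fit has 2 residual degrees of freedom, and the rest are borrowed from other genes. That interval therefore rests mostly on the variation of other genes and is no reliable measure of how the FOXE1 difference varies between patients. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and filterByExpr at a minimum of 10 counts, which left 22635 genes. It was two-sided with a Benjamini-Hochberg adjusted p threshold of 0.05 and had no covariate. A fit with the replicate number as a block, DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings, other filters and fits that left out libraries were alternatives. The tests, alternatives, gene lists and rule for naming genes were set before the data were examined, apart from the alternatives named in the closing section as added later. Alternatives planned for normalized values were not needed because the files hold counts.

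The series design says that the cells came from 3 patients, and P1 to P3 occur in both groups. No label states a paired model, so the pairing of libraries of one number is inferred. Deviations of log2 CPM, counts scaled to a common library size, from the group means correlated across genes at 0.74, 0.5 and 0.43 within replicates 1, 2 and 3. Among libraries of the other group, each library correlated best with that of its own number. However, siFOXE1 replicate 2 gave 0.34 with siControl replicate 3, and siFOXE1 replicate 3 gave 0.39 with siControl replicate 2. The correlations therefore set replicate 1 apart but part replicates 2 and 3 only weakly. The first principal component, with 55.63% of the variance, parted replicate 1 from replicates 2 and 3, and the next, with 20.44%, parted the groups. The biological coefficient of variation was 23.1% without the block and 7.5% with it, on 4 and 2 residual degrees of freedom. Values from the fit with the block are therefore printed where they change a call, and "paired fit" means that fit. No 2 libraries of a group agreed within sampling noise.

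Named genes were FOXE1, the thyroid list and, with an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same sign in all 3 pairs, the 10 genes with the largest log2 fold change in each direction. The unpaired fit gave no such gene, so all 20 places were filled from the paired fit. From each other list past the threshold, and from the p53 list, up to 4 members with the smallest unpaired p were named. Members named beyond this rule were chosen after their values were seen. The 23 lists held 458 entries, of which 420 were tested and 38 were not. They were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera tests on the residual degrees of freedom, 4 unpaired and 2 paired, so it has little power here. A list that does not pass it is therefore not shown to owe its preset result to correlation between genes. Yet the unpaired estimates for lists past the preset threshold ran from 0.04 to 0.9, all above the preset. They were 0.85 for ribosomal protein genes and 0.58 for TGF-beta response. Paired estimates lay below the preset for hypoxia (-0.02), cholesterol synthesis (-0.02) and heat shock (-0.06) and above it for the others. Where the estimate is above the preset, the preset p-value may be too small. Some genes that the rule names are not reported here, though counts of list members include them. Tables leave out 9 sex-linked genes.

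The fits were tested on simulated data with the real pair means, library sizes and paired dispersions, over 21726 genes of which 200 were changed. For the comparison labelled siFOXE1 against siControl, the unpaired fit recovered 0%, 38%, 70% and 86% of genes changed 1.5, 2, 3 and 4 times. The paired fit recovered 86%, 98%, 100% and 100%, with 15 false calls among 207. Changed genes were drawn only from those above a minimum mean simulated count, so these shares do not cover genes of low count. The counts were also drawn from the paired model itself, which favours the paired fit.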

Results

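Gene expression was measured by RNA-seq in 6 libraries of human primary thyroid cells from 3 patients, 3 labelled siFOXE1 and 3 labelled siControl. FOXE1 is a forkhead transcription factor needed for thyroid development, and the comparison asks which transcripts differ 24 h after an siRNA pool against it. Depth was 24119998 to 31560446 counts per library.

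FOXE1 (ENSG00000178919.8), the siRNA target, was higher in the libraries labelled siFOXE1, which goes against the labels. Its counts were 18153, 14082 and 16374 in replicates 1 to 3 labelled siFOXE1 and 9124, 7174 and 5575 in those labelled siControl. In CPM these were 645, 581 and 498 against 320, 240 and 216, with means of 575 ± 73.6 and 259 ± 54.3 (SD, n = 3 each). The log2 difference within pairs was 1.01, 1.27 and 1.21. The paired edgeR fit gave a fold of 2.24 (95% interval 2.01 to 2.50, adjusted p = 5.51e-08), and the unpaired fit a log2 fold change of 1.15 (SE 0.18) with an adjusted p of 0.462. An exact two-sided permutation test of the 6 values gave p = 0.1 and an exact sign-flip test of the 3 pairs p = 0.25, each the smallest its design allows. Because 6 of 6 deposited files are also named for the other siRNA, every direction below is that of the labels and would be reversed under the file names. PTCSC2, a non-coding neighbour of FOXE1 chosen after its values were seen, had 10.3, 11.1 and 9.22 CPM in the libraries labelled siFOXE1 and 7.99, 9.5 and 7.17 in those labelled siControl. It did not pass in the paired edgeR fit (log2 0.31, adjusted p = 0.0554), where lincRNA genes had a median of 0.23.

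**Figure D1:**
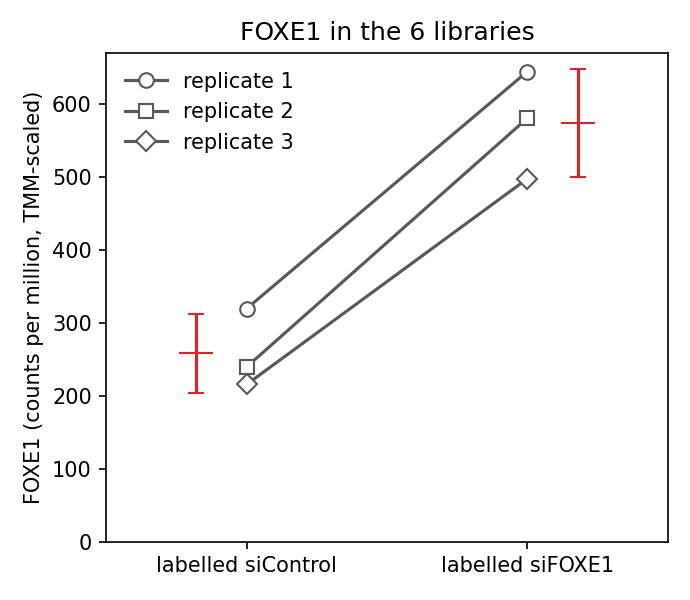
FOXE1 in TMM-scaled CPM (vertical axis) in each library, by label (horizontal axis), with lines joining libraries of one replicate number and red bars for the mean and SD (n = 3). All 3 libraries labelled siFOXE1, at 498 to 645, lie above the 3 labelled siControl, at 216 to 320.

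Several genes of thyroid hormone synthesis and differentiation were higher in the libraries labelled siFOXE1, as FOXE1 was, in the paired fit. SLC5A5, the iodide importer, was 2.3-fold higher (log2 1.20, SE 0.13, adjusted p = 8.25e-06, edgeR, paired), at 11.5 ± 8.21 against 4.84 ± 3.18 CPM (SD, n = 3). DIO2, which activates thyroid hormone, was 1.35-fold higher, and PAX8, a thyroid transcription factor, 1.23-fold. SLC26A4, HHEX, TSHR and DUOX1 were 1.16-fold to 1.22-fold higher. THRB, a thyroid hormone receptor gene, was 1.41-fold lower (adjusted p = 0.00432). The other 15 of 23 members did not pass, among them TG, the hormone precursor, with 32900 ± 19000 against 31600 ± 16900 CPM, NKX2-1 (log2 0.04), DUOX2 (0.01), IYD (0.06) and DIO1 (-0.10). Further members that did not pass were GLIS3 (0.19), SLC5A8 (0.30), TFF3 (-0.21), ANO1 (-0.06), DUOXA1 (-0.06), DUOXA2 (0.06), SLC26A7 (0.02) and THRA (0.01). Adjusted over the list alone, 8 were higher and 1 lower. In the same fit ribosomal protein genes, which move with RNA quality, had a median log2 fold change of -0.24 and mitochondrially encoded mRNAs one of 0.40. In paired DESeq2, DUOX1 (adjusted p = 0.0761), HHEX (0.11) and TSHR (0.0502) did not pass. Without replicate 2 the paired edgeR fit did not call these or SLC26A4 (0.102), PAX8 (0.126) and THRB (0.0721), and without replicate 3 it did not call DUOX1, HHEX, TSHR (0.127 to 0.368) and SLC26A4 (0.0802). The list as a whole did not pass camera (adjusted p = 0.631, or 0.224 with the pairs), except without siFOXE1 replicate 1 (0.0335) and, with the pairs, in protein-coding genes alone (0.00753). With all libraries and an estimated correlation the adjusted p was 0.897, or 0.861 with the pairs. Unpaired edgeR, DESeq2 and limma-voom called 0 members (1 at an unadjusted p under 0.05 in each), and unpaired edgeR without replicate 1 called SLC5A5 (0.00587), THRB (0.00513) and SLC5A8 (0.0292).

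Over all genes, the paired edgeR fit placed 1371 genes higher and 1931 lower in the libraries labelled siFOXE1, of 22635 tested. Changes were mostly small, with a median absolute log2 fold change of 0.39, and 199 of the higher and 47 of the lower genes reached 2-fold. Of the 3302 genes, 3261 had one sign in all 3 pairs. The paired fit selected these genes on the same pair differences, so that agreement is largely built in and is no further support. The unpaired edgeR fit called 0 genes, with 2171 at an unadjusted p under 0.05, against 71 with DESeq2 and 0 with limma-voom. Leaving out replicate 2 from the paired fit left 1723 calls, and leaving out replicate 1 from the unpaired fit gave 702. The split of higher against lower moved with the scaling: upper-quartile factors gave 1712 higher and 1077 lower, where TMM gave 1371 and 1931. With TMM, 12.37% of all protein-coding genes were called lower and 4.89% higher, which is the background for the list counts below.

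The largest decreases in the libraries labelled siFOXE1 were those of GDF6, AQP3, ACTC1, IVL and OASL. GDF6 (ENSG00000156466.9), a bone morphogenetic protein, was 3.16-fold lower (log2 -1.66, SE 0.11, adjusted p = 5.51e-08, edgeR, paired), at 6.63 ± 0.806 against 20.9 ± 2.23 CPM (SD, n = 3). AQP3, a water and glycerol channel, was 3-fold lower, ACTC1, cardiac actin, 2.79-fold, and IVL, a protein of the cornified envelope, 2.6-fold. OASL, an interferon-induced gene, was 2.59-fold lower and NGFR, the low-affinity neurotrophin receptor, 2.41-fold. PLCXD3, IGFBP3, RGS4 and RAET1L were 2.15-fold to 2.23-fold lower. IGFBP3, which binds insulin-like growth factors, was the most abundant of these, at 581 ± 442 against 1140 ± 546 CPM. Paired DESeq2 gave no adjusted p for AQP3, NGFR and PLCXD3, whose log2 fold changes there were -1.64, -1.33 and -1.17.

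Besides FOXE1 and SLC5A5, the largest increases included RTN4RL2, a Nogo receptor relative, at 2.3-fold (adjusted p = 1.05e-05, edgeR, paired). The non-coding LINC01886 was 2.38-fold higher, AL445309.1 2.32-fold and AP006248.4 2.29-fold. FP236383.2 (2.89-fold), FP236383.3 (2.71-fold), FP671120.3 (2.31-fold) and MIR3648-2 (2.7-fold) lie in near-identical ribosomal DNA repeats, so their reads may have been shared between copies and their values are uncertain. MIR3648-2, with pair differences of 2.48, 1.32 and 0.09, did not pass without replicate 1 (adjusted p = 0.0984) or in paired DESeq2 (0.164), and neither did FP671120.3 in paired DESeq2 (0.0836). AL445309.1 and AP006248.4 got no adjusted p there. AL445309.1 is annotated as antisense and AP006248.4 as sense intronic, so their counts may include reads of the overlapping gene.

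Hypoxia and glycolysis genes were lower in the libraries labelled siFOXE1, with 15 of 17 tested members past the threshold in the paired edgeR fit (15 adjusted over the list alone) and a median log2 fold change of -0.43. ADM, a vasodilator peptide induced by low oxygen, was 2.01-fold lower (adjusted p = 9.16e-06), EGLN3, an oxygen sensor, 1.41-fold, NDRG1 1.35-fold and KDM3A, a histone demethylase, 1.21-fold. EGLN3 and KDM3A did not pass without replicate 2 (0.164 and 0.0927) or 3 (0.0802 and 0.053), nor EGLN3 in paired DESeq2 (0.0596). The camera adjusted p was 1.37e-06, and the adjusted p was 0.532 with an estimated correlation, which was 0.3. With the pairs that adjusted p was 0.47, although the correlation estimated there was -0.02. The hypoxia list was the one list past fry's threshold in the paired fit (adjusted p = 0.048). In the same fit ribosomal protein genes, which move with RNA quality, were lower too (21 of 31, median log2 -0.24), and mitochondrially encoded mRNAs higher (median 0.40, or 0.24 with the length and GC trend removed).

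Inflammatory genes and genes induced by TGF-beta were lower too, alongside the ribosomal protein genes (median log2 -0.24). Of 19 NF-kB and cytokine genes, 9 were lower and 0 higher (12 adjusted over the list alone), with CCL2 2.05-fold, LIF 1.58-fold, CXCL2 1.49-fold and CXCL1 1.41-fold lower. Their camera adjusted p was 1.53e-06, and the adjusted p was 0.506 with an estimated correlation. Of 18 TGF-beta response genes, 10 were lower (11 adjusted over the list alone), among them TAGLN (1.53-fold), PMEPA1 (1.48-fold) and ACTA2 (1.4-fold, but 0.117 for the adjusted p without replicate 2). TGFB1, the ligand itself, was the 1 member that was higher (log2 0.61). That list had a camera adjusted p of 0.000837, and an adjusted p of 0.733 with an estimated correlation. In unpaired fits it did not pass without siFOXE1 replicate 3 (0.0721) or siControl replicate 1 (0.0576). Of 20 immediate early genes, IER3 (1.67-fold), DUSP1 (1.4-fold), DUSP5 (1.34-fold) and JUNB (1.29-fold) were lower and DUSP6 (log2 0.29) and EGR1 (0.27) higher (4 and 2 adjusted over the list alone). The camera adjusted p there was 0.032, and the adjusted p was 0.532 with an estimated correlation. It was 0.178 without siFOXE1 replicate 3, 0.114 and 0.0545 without siControl replicates 3 and 2, and 0.353 without both libraries of replicate 3. It was 0.163 with a mean log2 CPM of at least 1 and, with the pairs, 0.0453 with all libraries, 0.299 in protein-coding genes alone, 0.131 with length and GC removed, and 0.0742 and 0.315 without replicates 2 and 3. JUNB did not pass without replicate 3 (0.11). The immediate early list's median of -0.11 was -0.05 with upper-quartile factors.

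Keratins led the decrease among epithelial markers, whose median of -0.22 lay near that of the ribosomal protein genes (-0.24). KRT19 was 1.64-fold, KRT7 1.48-fold, KRT8 1.44-fold and KRT18 1.43-fold lower, and 8 of 20 members were lower (10 adjusted over the list alone). CDH1, the epithelial cadherin, did not pass (log2 -0.14, adjusted p = 0.207, edgeR, paired). Of 15 mesenchymal transition genes, CDH2 (1.45-fold), FN1 (1.41-fold), SPARC (1.32-fold) and ITGA5 (log2 -0.23) were lower (5 adjusted over the list alone), while MMP14 did not pass (log2 -0.21). Camera gave adjusted p = 0.00097 for the epithelial and 0.0158 for the mesenchymal list, and the adjusted p was 0.532 for both with an estimated correlation. The mesenchymal list did not pass without siControl replicate 1 (0.136), siFOXE1 replicate 2 (0.0788) or 3 (0.0989), or both libraries of replicate 3 (0.0591). With the pairs it did not pass without replicate 3 (0.0637) or in protein-coding genes alone (0.0823). Upper-quartile factors gave medians of -0.16 for the epithelial and -0.1 for the mesenchymal list, against -0.22 and -0.16 with TMM. Markers of other cell types did not pass camera with all libraries. With the pairs and without replicate 3, the fibroblast (0.00384) and endothelial (0.0415) lists passed as higher, and with the pairs, all libraries and an estimated correlation the adjusted p was 0.911 and 0.989. Of 16 fibroblast markers, COL1A1 (log2 0.51) and COL5A1 (0.46) were higher (2 adjusted over the list alone, camera adjusted p = 0.469), and of the others 0 of 13 endothelial (0.984) and 0 of 7 leukocyte markers (0.726) passed.

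Of 28 p53 target genes, with a median log2 fold change of -0.22 beside -0.24 for ribosomal protein genes, 9 were lower (14 adjusted over the list alone), with PLK2 1.49-fold, PHLDA3 1.28-fold, TP53I3 1.27-fold and CCNG1 1.19-fold lower. CCNG1 did not pass without replicate 1 (0.0971) or 2 (0.0968), nor TP53I3 without replicate 2 (0.0542). Camera gave them an adjusted p of 5.24e-05, and the adjusted p was 0.532 with an estimated correlation. Of 14 heat shock genes, DNAJB1 (1.31-fold), HSPB1 (1.23-fold), DNAJA1 (1.21-fold), HSP90AB1 (1.21-fold) and CRYAB (log2 -0.35) were lower (5 adjusted over the list alone). Of 17 cholesterol synthesis genes 7 were lower (7 adjusted over the list alone), including FDPS (1.22-fold) and LSS (1.15-fold), whereas SC5D (log2 -0.14) did not pass. List medians depended on the scaling. With upper-quartile factors they were -0.16 for p53 targets, -0.08 for heat shock and -0.11 for cholesterol synthesis, against -0.22, -0.14 and -0.17 with TMM. The camera adjusted p was 0.0227 for heat shock and 0.0477 for cholesterol synthesis, and with an estimated correlation the adjusted p was 0.532 and 0.86. HSPB1, DNAJA1, HSP90AB1, FDPS and LSS did not pass in the paired fit without replicate 2 (0.0698 to 0.227) or 3 (0.0681 to 0.378), nor LSS without replicate 1 (0.116). With a mean log2 CPM of at least 1 neither list passed (0.163 for both), cholesterol synthesis did not with DESeq2 size factors (0.0549), and heat shock did not with the pairs in protein-coding genes alone (0.0954). In unpaired fits heat shock did not pass without siControl replicate 1 (0.139), siFOXE1 replicate 2 (0.0685) or 3 (0.0989), or both libraries of replicate 2 (0.0655). Cholesterol synthesis, also unpaired, did not without siControl replicate 1 (0.852), siFOXE1 replicate 2 (0.0685) or 3 (0.769), or both libraries of replicate 3 (0.079). Among 33 cell cycle genes, MCM6 (log2 0.31) and CDC20 (0.25) were higher (0 adjusted over the list alone) and the list did not pass (adjusted p = 0.96), with a median of -0.01 that was 0.05 with upper-quartile factors. It passed as lower without siFOXE1 replicate 1 (0.00117) and as higher without siControl replicate 1 (0.00433), and the adjusted p with all libraries and an estimated correlation was 0.993. Of 25 interferon response genes, OASL and RSAD2 (log2 -0.76) were lower (2 adjusted over the list alone, camera adjusted p = 0.186), and the list passed without siFOXE1 replicate 2 (9.98e-05), siControl replicate 2 (0.05 when rounded) or both libraries of replicate 2 (1.5e-05, or 8.5e-05 with the pairs). With all libraries and an estimated correlation its adjusted p was 0.86, or 0.911 with the pairs.

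Mitochondrially encoded mRNAs were higher in the libraries labelled siFOXE1, with 9 of 13 higher and MT-ND3 lower (log2 -0.39), or 10 higher and 1 lower adjusted over the list alone. MT-CYB was 1.7-fold, MT-ND1 1.5-fold, MT-ND5 1.43-fold and MT-ATP8 1.32-fold higher, from libraries in which all genes of the mitochondrial genome, ribosomal and transfer RNA included, held 0.57% to 1.3% of counts. The list's median of 0.40 was 0.24 with the length and GC trend removed, where MT-ATP8 did not pass (adjusted p = 0.23), nor did it without replicate 1 (0.14) or 2 (0.0554). Ribosomal protein genes were lower, 21 of 31 in the paired edgeR fit (28 adjusted over the list alone), with RPS3 1.32-fold, RPL11 1.28-fold and RPS9 1.23-fold lower (RPS9 0.0833 without replicate 1). Both kinds of transcript move with RNA quality and library preparation. The camera adjusted p was 0.032 for the mitochondrial and 1.32e-08 for the ribosomal list, and with an estimated correlation the adjusted p was 0.86 and 0.695. In unpaired fits the mitochondrial list did not pass without siControl replicate 1 (0.805), siFOXE1 replicate 2 (0.192) or 3 (0.257), or both libraries of replicate 1 (0.102) or 2 (0.219). The unpaired edgeR fit of all libraries called 0 members of any list over all genes, with 50 at an unadjusted p under 0.05, against 7 in unpaired DESeq2, 0 in limma-voom and 47 in unpaired edgeR without replicate 1. In unpaired fits, single libraries left out gave 5 lists past camera's threshold (without siFOXE1 replicate 3) to 14 (without siFOXE1 replicate 1), against 11 with all libraries. With the pairs kept, camera called 12 lists, and 11, 12 and 12 without replicates 1, 2 and 3.

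**Figure D2:**
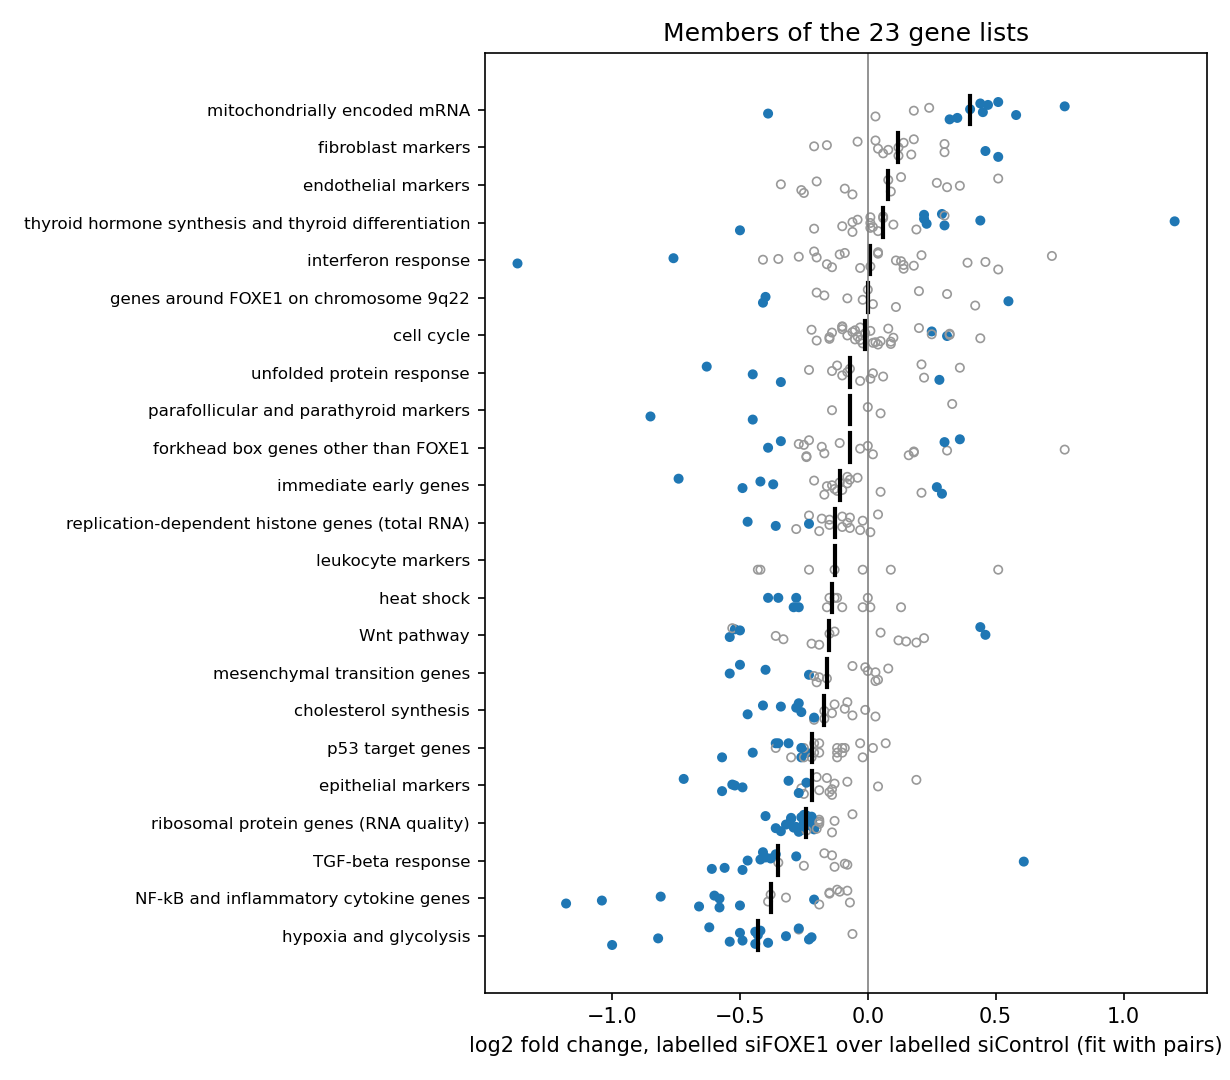
Paired log2 fold changes (horizontal axis, labelled siFOXE1 over labelled siControl) of the tested members of each gene list (vertical axis). Filled points passed the adjusted p threshold of 0.05, open points did not, and black bars are medians, from -0.43 for hypoxia and glycolysis to 0.4 for mitochondrially encoded mRNA.

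Genes of types other than protein-coding had higher log2 fold changes on the whole than protein-coding genes in the libraries labelled siFOXE1. Of 14942 protein-coding genes, 731 were higher and 1849 lower, with a median log2 fold change of -0.05 in the paired edgeR fit. That side of 0 depended on the scaling, as upper-quartile factors gave 1017 higher and 1042 lower and a median of 0.01. Of 7693 genes of other types, 640 were higher and 82 lower, with a median of 0.23, or 0.29 with upper-quartile factors and 0.12 with length and GC removed. These include pseudogenes, among them 1516 processed ones with a median of 0.24, and genes without an annotated type. Medians were 0.23 for antisense genes and for lincRNA and 0.28 for sense intronic genes, above 0 in 3 of 3 pairs, while small nucleolar RNA (0.06) differed in sign between pairs. With length and GC removed they were 0.13 for antisense, 0.14 for lincRNA and 0.12 for sense intronic genes. Fitted alone, protein-coding genes gave 1107 higher and 1132 lower, with a median of 0.01.

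**Figure D3:**
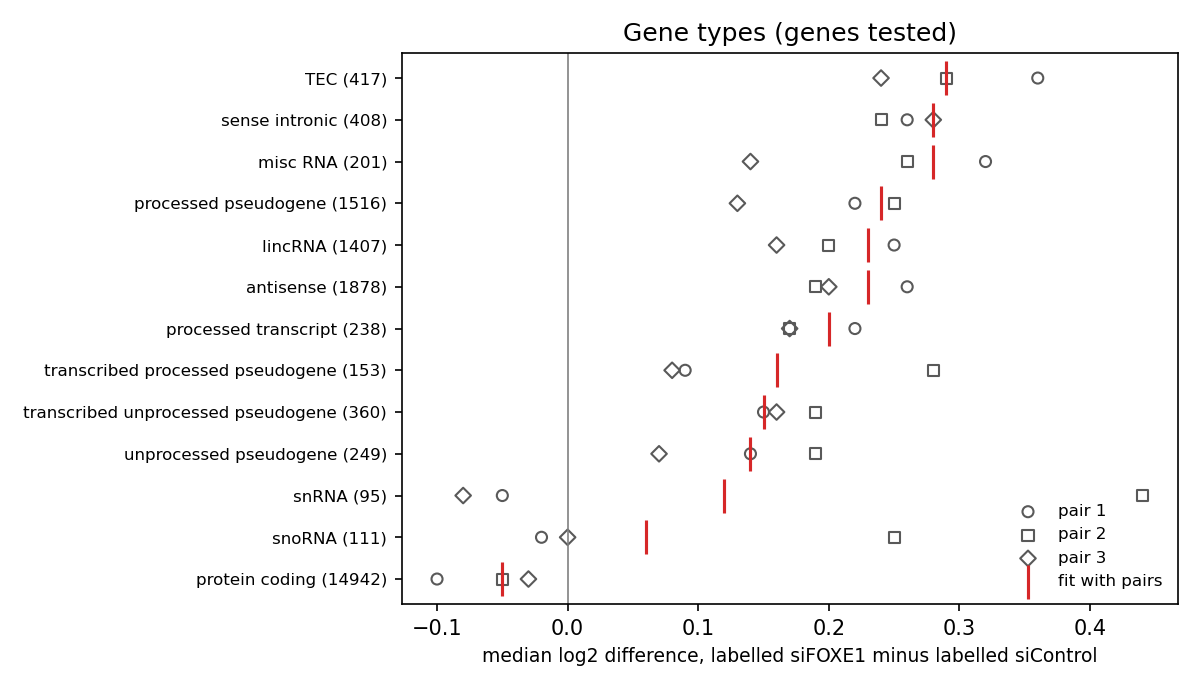
Median log2 difference (horizontal axis, labelled siFOXE1 minus labelled siControl) by annotated gene type, with the number of genes tested (vertical axis). Open symbols are the 3 pairs and red bars the paired fit. With TMM factors, protein-coding genes lie below 0 in each pair and lincRNA and antisense genes above it.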

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

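Fits on protein-coding genes alone, with the length and GC trend removed, with the block and another scaling or filter, and with the block without 1 replicate number were added after seeing the data. FOXE1 kept its sign in every fit, with a log2 fold change of 1.03 (without siControl replicate 3) to 1.33 (without siControl replicate 1) when libraries were left out. It passed the threshold in unpaired edgeR without replicate 1 (1.24, adjusted p = 0.00064), in unpaired DESeq2 (1.14) and with the replicate block in edgeR (1.16), DESeq2 (1.15) and limma-voom (1.16). With the block it also passed for protein-coding genes only (1.23), without replicate 1 (1.24), 2 (1.12) or 3 (1.14), with DESeq2 size factors (1.15), upper-quartile factors (1.22), the stricter filter (1.21) and length and GC removed (1.17).

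The count of genes was 0 in the unpaired edgeR fit, with 2171 at an unadjusted p under 0.05. Unpaired DESeq2 gave 71 (27 higher, 44 lower). Fits that left out libraries gave 0 to 702 (0 to 284 higher, 0 to 418 lower), the highest without replicate 1. The replicate block gave 3302 (1371 higher, 1931 lower) in edgeR, 2185 (533, 1652) in DESeq2 and 3297 (1325, 1972) in limma-voom. Block fits gave 2239 (1107, 1132) for protein-coding genes only, 3543 (1236, 2307) with DESeq2 size factors, 2789 (1712, 1077) with upper-quartile factors, 2595 (1346, 1249) with a mean log2 CPM of at least 1 and 4325 (1357, 2968) with length and GC removed. Without replicates 1, 2 and 3 they gave 2410 (1022, 1388), 1723 (692, 1031) and 2492 (1086, 1406). Fewer libraries entered these last fits. DESeq2 gave no adjusted p to 9655 of 22635 genes with the block and to 4833 without it, so fewer genes could be called there. The cause of the other differences was not tested. Genes called in the paired edgeR fit and in another block fit had opposite signs in 0 cases. Those fits share libraries and cover only genes called in both, so this is no separate evidence. Depth of 24119998 to 31560446 counts limits genes of low count most. Of the 10 splits of the 6 libraries, 10 had at least as many genes as the real 0, with 0 as the highest other. A real count of 0 fixes that outcome in advance, so it decides nothing. Of the 4 splits that part all 3 pairs, 1, the real one, had as many as the real 3302, with 0 as the highest other. Those 4 splits are too few for a share under 0.05. The other 3 of those 4 each exchange the groups within 1 pair.

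The lists past the threshold numbered 11 with camera, 0 with an estimated correlation, 0 with fry, 1 with the replicate block in fry and 0 with the block and an estimated correlation. A mean log2 CPM of at least 1 gave 8, with cholesterol synthesis, heat shock and immediate early genes not past it and leukocyte markers not tested, and DESeq2 size factors gave 10, without cholesterol synthesis. With the block, protein-coding genes only gave 9, with the thyroid list added and heat shock, immediate early, mesenchymal and histone genes (0.15) not past it, and length and GC removed gave 11, without immediate early genes. Leaving out libraries gave 5 to 14 without the block, and leaving out replicates 1, 2 and 3 with the block in camera gave 11, 12 and 12. With the block, the histone list did not pass without replicate 1 (0.58). The block in camera added the histone list and changed no other list's call.

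Of the 20 genes with the largest paired changes, 13 passed in paired DESeq2, 2 did not and 5 got no adjusted p. Of 66 named genes past it in paired edgeR, 21 did not pass in at least 1 of the other fits with the block: 9 in DESeq2, 1 in limma-voom, 4 for protein-coding genes only, 5, 17 and 12 without replicates 1, 2 and 3, 3 with DESeq2 size factors, 7 with upper-quartile factors, 3 with the stricter filter and 1 with length and GC removed. The unpaired edgeR fit called none, so calls could only be gained against it, as in 717 values of named genes. For lists 18 values gained the threshold and 77 lost it. Sign changes occurred in 52 of 2180 values of named genes, from 12 genes, with 0 past the threshold, and in 41 of 482 values of lists, from 10 lists, with 1 past the threshold. The cause was not tested. In unpaired fits THRA was -0.002 with DESeq2 size factors and -0.002 in DESeq2, and DUOXA1 0.001 with upper-quartile factors. With the block, DESeq2 gave TG -0.003, THRA -0.003 and DUOX2 -0.007, as did edgeR with DESeq2 size factors (TG -0.003, THRA -0.003, DUOX2 -0.007). Protein-coding genes only gave ANO1 0.002 and DUOXA1 0.003, and SLC26A7 was -0.017 with length and GC removed. Block fits gave DUOXA1 0.02 without replicate 1, TG -0.026, ANO1 0.039, NKX2-1 -0.063 and DUOX2 -0.083 without replicate 2, and TG -0.001, DUOXA2 -0.077 and SLC26A7 -0.135 without replicate 3. Leaving out libraries in unpaired fits, log2 fold changes ran from -0.435 to 0.57 for IYD, -0.33 to 0.46 for TG, -0.001 to 0.62 for SLC26A4, -0.092 to 0.13 for THRA, -0.22 to 0.121 for ANO1 and -0.062 to 0.15 for NKX2-1. They ran from -0.13 to 0.021 for DUOXA1, -0.099 to 0.31 for DUOXA2, -0.186 to 0.21 for DUOX2, -0.122 to 0.24 for SLC26A7, -0.51 to 0.142 for TFF3 and -0.32 to 0.118 for DIO1.

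Adjusted p values of lists whose direction changed were, for cell cycle, 0.948 with fry, 0.979 with the replicate block in camera, 0.797 with the block in fry, 0.983 with DESeq2 size factors, 0.714 with the stricter filter, and with the block 0.173 for protein-coding genes only, 0.692 with length and GC removed, 0.989 with an estimated correlation, 0.987 without replicate 1 and 0.566 without replicate 2. The genes near FOXE1 had 0.861 with the block in fry, 0.905 for protein-coding genes only, 0.842 with length and GC removed and 0.731 without replicate 3. Other forkhead genes had 0.905 for protein-coding genes only and 0.987 without replicate 1, endothelial markers 0.843 without replicate 1 and 0.353 without replicate 2, and leukocyte markers 0.33 without replicate 3. Leaving out libraries without the block gave 0.00117 to 0.99 for cell cycle, whose lowest value came without siFOXE1 replicate 1, as lower, while without siControl replicate 1 it passed as higher (0.00433). Such ranges were 0.123 to 0.933 for endothelial, 0.0591 to 0.99 for fibroblast, 0.212 to 0.851 for leukocyte markers, 0.39 to 0.978 for genes near FOXE1, 1.5e-05 (without replicate 2) to 0.99 for interferon response, 0.000418 (without siControl replicate 2) to 0.647 for histone genes, 0.0335 (without siFOXE1 replicate 1) to 0.9 for thyroid genes and 0.0245 (without siFOXE1 replicate 2) to 0.836 for the unfolded protein response.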

Other observations

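Tests in this part of exchanged labels, a genuine rise, culture wells, and gene length, GC content or RNA class were chosen after the results they bear on were seen. Directions are those of the labels, against which FOXE1 went. Among unfolded protein response genes, ATF4 (log2 -0.45), CHAC1 (-0.63) and ASNS (-0.34), which act in the amino acid branch of the stress response, were lower and the chaperone gene HSPA5 (0.28) was higher in the paired edgeR fit, of 17 tested. Adjusted over the list alone, 4 were higher and 3 lower, and the list did not pass camera (adjusted p = 0.316), except without siFOXE1 replicate 2 (0.0245), and the adjusted p with all libraries and an estimated correlation was 0.86. CALCA, the calcitonin gene (log2 -0.45), and CALCB, its relative that encodes a calcitonin gene-related peptide (-0.85), were lower, 2 of 6 parafollicular and parathyroid markers (2 adjusted over the list alone, camera adjusted p = 0.707).

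Of 17 Wnt pathway genes, DKK3 (log2 -0.52), WNT5B (-0.50) and DKK1 (-0.54) were lower and TCF7L1 (0.46) and WNT4 (0.44) higher (3 and 2 adjusted over the list alone, camera adjusted p = 0.471). Of 20 forkhead genes other than FOXE1, FOXP4 (0.36) and FOXK1 (0.30) were higher and FOXN2 (-0.39) and FOXN3 (-0.34) lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.449). Of 13 genes near FOXE1, TMOD1 (0.55) was higher and TBC1D2 (-0.41) and CORO2A (-0.40) lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.726). Of 18 histone genes, HIST1H2BG (-0.36), HIST1H2AB (-0.47) and HIST1H4H (-0.23) were lower (4 adjusted over the list alone). That list passed camera with the block (adjusted p = 0.0245), though not without replicate 1 (0.58) or for protein-coding genes only (0.15). It did not pass without the block (0.0869), where it passed without siFOXE1 replicate 1 (0.00216), siControl replicate 2 (0.000418) or 3 (0.0131), or both libraries of replicate 2 (0.00917), and the adjusted p was 0.861 with the block and an estimated correlation. These members were chosen after their values were seen.

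FOXE1 was higher in the library labelled siFOXE1 in 3 of 3 pairs. An exchange within 1 pair only is excluded, since the smallest pair difference was 1.01 on the log2 scale and all 3 differences have one sign. That the labels of the 2 groups were exchanged in all 3 pairs is a candidate explanation, for which the separate evidence is that 6 of 6 files are named for the other siRNA. A rise of the transcript after the siRNA would give the same value (log2 1.16), so it cannot be told apart from exchanged labels, because the counts hold no other marker of which siRNA a well received.

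Genes annotated with a type other than protein-coding, here called non-coding though they include pseudogenes, had a median log2 fold change 0.28 above that of protein-coding genes. Genes without an annotated type were left out of this comparison. Low expression alone is argued against, since the difference from protein-coding genes of matched mean log2 CPM was 0.14 (95% bootstrap interval 0.12 to 0.16 over genes). Gene length and GC content are argued against as the whole cause, as 0.18 (0.17 to 0.19) was left after their trend was removed, though both steps took away part of the gap. The steps were not applied together, so whether they jointly account for the gap was not tested. Both intervals resample genes and hold no variation between pairs. A larger share of nuclear or unprocessed RNA could not be decided. The 6 nuclear non-coding RNAs examined had a median of 0.16, just above the 0.15 set beforehand. NEAT1 (0.41) and KCNQ1OT1 (0.38) passed the threshold, PVT1 (0.23), MALAT1 (0.09) and TUG1 (0.04) did not, and MIAT was at -0.23. These RNAs belong to the non-coding genes whose shift was to be explained. Genes other than protein-coding had a median of 0.23, so the 0.16 cannot tell a nuclear share from the shift itself. Whether such a share would come from RNA extraction or from the siRNA was not tested.

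Hypoxia and glycolysis genes were lower in each pair. The shift between RNA classes, gene length and GC content are argued against, as the list's median was -0.41 in protein-coding genes with those trends removed, with pair medians of -0.38, -0.38 and -0.42. The expression level of its genes is argued against as well: its percentile was 0 among 10000 random lists matched on mean log2 CPM, of which the lowest had a median of -0.32. A difference between culture wells such as density or oxygen remains possible, because a list median below 0 in 3 of 3 pairs cannot be told apart from a handling difference shared by each arm. RNA quality, with ribosomal protein genes at a median of -0.24 and mitochondrial mRNA at 0.40 (0.24 with length and GC removed), and an effect of FOXE1, in the direction the labels or the file names would give, stay open as well and were not tested.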
